A study of Mus musculus with 2 samples.

How the data were processed

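The series holds 2 samples of 4T1 cells, a mouse mammary carcinoma line, labelled wild type and knockout, with 1 sample per group; the series' design text names Cd28 as the gene knocked out. Poly(A) RNA was purified with oligo-dT beads, fragmented, reverse transcribed with random hexamers and amplified by PCR, per the labels' protocols. The protocol mentions neither a strand-marking step nor molecular identifiers, so reads are not independent molecules and every interval given here covers counting error only.

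The deposited table gives whole-number read counts per gene, not normalized, beside each gene's position, strand, length, biotype and description. Per the submitters' processing notes, CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used, with genome build mm10. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Of the 54532 gene IDs in the table, 54495 are also in GENCODE vM21, an annotation of the same build (GRCm38). The position was identical for 53585 of them, and the length equalled the merged exon length for 53411. All coordinates below are those of the deposited table, counted from 1. No row lacked a gene name.

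The table has a count column headed KO, whose name is the title of the knockout sample. It has 1 other column of per-sample values, headed PX. That name matches no label of the wild-type sample, and assigning it by elimination would be a guess, so the column was not used and the wild-type library was not analysed here. The comparison of knockout with wild type that was fixed before the data were examined was therefore not made: no ratio, no count of higher or lower genes, no chromosome median and no other setting of that comparison was computed. The text describes the levels in 1 library, which has no replicate; no difference between conditions follows from them.

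The knockout library held 15565990 counted reads. Levels are given as reads per 1000000 counted reads (CPM), computed here from the deposited counts, with exact Poisson 95% intervals. For a count of 0 the one-sided 95% limit of 3 reads is given, which is 0.193 CPM at this depth; the two-sided exact interval ends at 3.69 reads, or 0.237 CPM. To rank genes against each other, counts were divided by the deposited gene length and scaled to sum to 1000000 (TPM). A gene's percentile is the percentage of the 11497 protein-coding genes with at least 10 reads that had a lower TPM. A gene was called detected at 10 reads or more, a threshold chosen after the file was seen. The interval, the measure of shared sequence and the rank test were tested on simulated data. In Poisson draws for 13793 genes, 95.5% of intervals held the true mean. The own-sequence percentage was recovered within 0.222 points in 40 simulated transcripts. Of 20 rank tests on unrelated values, 0 gave a p under 0.05. These checks test the computation only: the draws were Poisson, as the interval assumes, and 20 tests cannot give an error rate.

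The 34 gene lists were fixed before the data were examined. Genes named from each are up to 2 of its members with the most reads, without correction for length, following the rule fixed beforehand for lists where no ratio passes, together with Cd28 and Cd274. The part of the rule that ranked genes by ratio had no values to rank, and the 12 protein-coding genes with the most reads were named in its place. Any other gene was chosen after its values were seen. A symbol listed under more than 1 ID (Aldoa, Atp5o, Ddit3) was taken at its lowest Ensembl ID. The percentage of 100-base or 50-base stretches of a transcript found in no transcript of another gene was computed from the GENCODE vM21 transcripts, for the protein-coding transcript with the longest coding part, on either strand. The share of a gene's merged exons covered by another gene's exons came from the same annotation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and scipy 1.17.1 were used.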

Results

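Poly(A) RNA of 4T1 cells carrying a Cd28 knockout was profiled by RNA sequencing. 4T1 is a mammary carcinoma line of BALB/c mice that is widely used as a transplantable model of breast cancer. CD28 is best known as a costimulatory receptor of T cells, and the series' title places it inside cancer cells, acting on PD-L1, the ligand of the inhibitory receptor PD-1. The labels give 1 wild-type and 1 knockout sample. Only the knockout library was analysed, because the table's other count column carries a name that matches no sample label. The values are therefore levels in a single library without a replicate, and the effect of the knockout was not measured here. The library held 15565990 counted reads, of which 96.2% fell on protein-coding genes and 1.35% on the mitochondrial genome. Of 22046 protein-coding genes listed, 11497 (52.1%) had at least 10 reads and 8253 had 0. The median of the detected protein-coding genes was 587 reads, or 37.7 CPM and 24.4 TPM.

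Few reads fell on the targeted gene, fewer than the 10 at which a gene was called detected. Cd28 (ENSMUSG00000026012, chromosome 1, 60716800 to 60773359, plus strand, mm10, protein-coding, 7 merged exons) had 8 reads, which is 0.514 reads per 1000000 counted reads (CPM) (exact Poisson 95% interval 0.222 to 1.01). Its TPM of 0.249 lay at percentile 0.296 of the detected protein-coding genes (percentile 0.0087 to 1.32 over the counting interval), and at 11.01 when ranked among those with at least 1 read. The count covers the whole gene, so it does not show whether the reads came from an edited or an intact transcript. Without a wild-type level the count cannot check the label, and a small insertion or deletion need not lower a gene's read count. Within 1 Mb of Cd28, the other receptor genes of the family, Ctla4 and Icos, had 0 reads each, which allows up to 0.193 CPM. Neighbouring protein-coding genes of other function ranged from 0 reads for Pard3b and 4 for Ica1l to 2843 for Nop58, a nucleolar ribonucleoprotein, and 2868 for Bmpr2, a BMP receptor. By TPM, Carf lay at percentile 11.5, Raph1 at 47.3, Bmpr2 at 57.4 and Cyp20a1, the highest of these protein-coding genes, at 80.6. The processed pseudogene Eif4a-ps4, upstream of Cd28 on the same strand (60703932 to 60705149), had 1664 reads and a TPM at percentile 96.7. Its count does not show transcription at this locus. For processed pseudogenes with at least 1000 reads, misplaced reads of the parent mRNAs are a candidate explanation, taken up below.

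PD-L1 mRNA was detected below the median of detected protein-coding genes. Cd274, which encodes PD-L1 (chromosome 19, 29367455 to 29388095), had 82 reads, which is 5.27 CPM (4.19 to 6.54), at percentile 14.4 (12.3 to 16.8), or 28.6 when ranked among protein-coding genes with at least 1 read. Another gene's exons cover 14.1% of its merged exon length. In the list of immune checkpoint and B7/CD28 family genes, 14 of the 31 members in the table were detected and 11 had 0 reads. The 2 with the most reads were Cd47, the "do not eat me" signal read by macrophages, at 219.9 CPM (213 to 227), and Cd24a, a ligand of Siglec receptors, at 218 (211 to 226). Among the ligands, Cd276 (B7-H3) had 102 CPM (96.7 to 107), and Pvr, a ligand of TIGIT, had 109.9 (105 to 115). Both intervals lie above that of Cd274. Pdcd1lg2, which encodes the second PD-1 ligand, had 1 read, Cd80 had 4, and Cd86, both of these being CD28 ligands, had 0. Pdcd1, Ido1 and Cd200 also had 0 reads.

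Genes reported to control PD-L1 were detected throughout: all 37 of the list had at least 10 reads, and 28 exceeded the median TPM of detected protein-coding genes. Zfp36l2, which binds AU-rich mRNA, had 538 CPM and Ybx1, a cold-shock-domain RNA-binding protein, 503. Snd1, a nuclease that binds RNA, had 157 (151 to 164), and Cmtm6, which keeps PD-L1 at the cell surface, had 1103 reads. Components of CD28 signalling were split. Of 27 members, 19 were detected, with the most reads on Akt1 (567 CPM) and the phosphatase subunit Ppp2r1a (269), whereas Vav1, Prkcq, Lat, Lcp2 and Grap2, which serve antigen-receptor signalling in lymphocytes, had 0 reads each and Lck had 33.

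**Figure D1:**
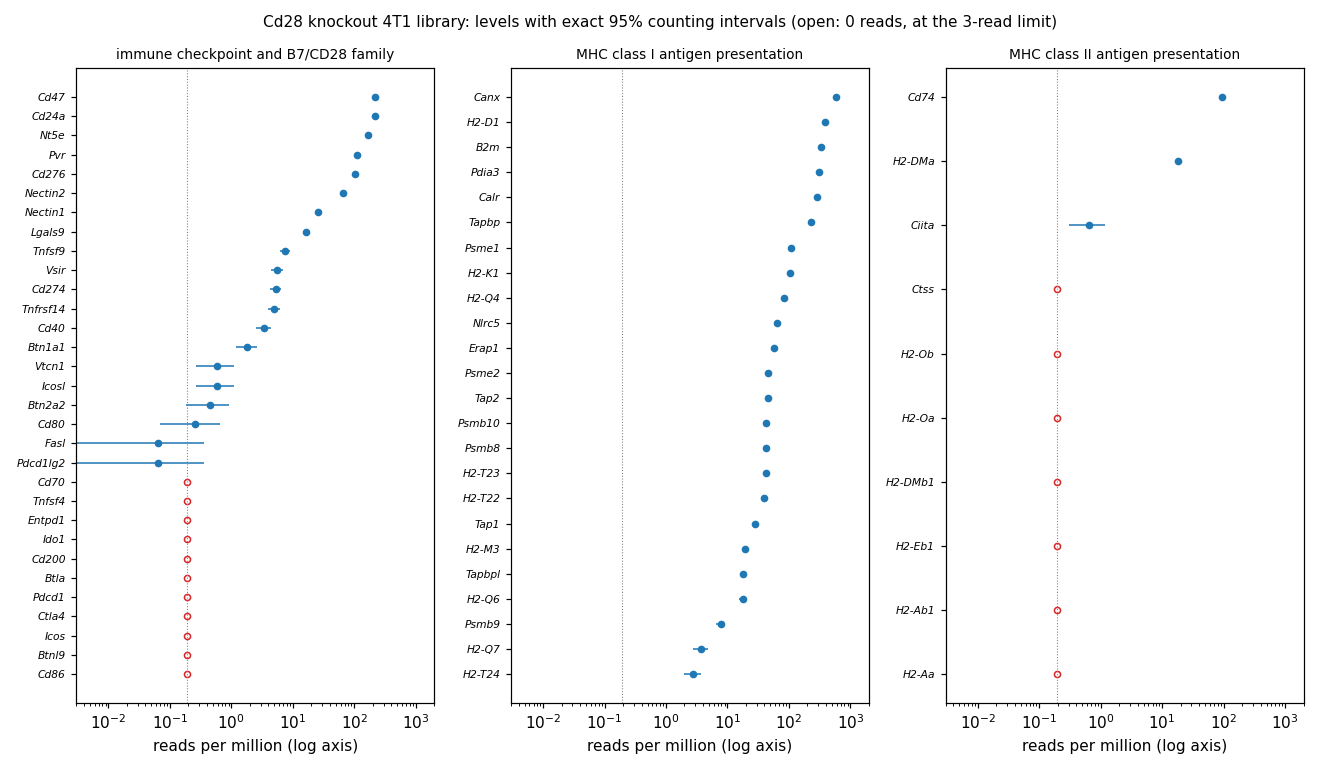
CPM (log axis) of each gene of 3 lists in the knockout library; filled points are the values, bars their exact Poisson 95% intervals (not visible where narrower than the point, and running off the axis at 1 read), and open points genes with 0 reads, drawn at the 3-read limit of 0.193 marked by the dotted line. Cd274 sits at 5.27, below Cd276 at 102, and the classical class II genes are at the limit.

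Class I antigen presentation genes were expressed and classical class II genes were not detectable at this depth. All 24 class I members in the table were detected and 17 exceeded the median TPM. Canx, a chaperone of class I folding, had 587 CPM and the heavy chain gene H2-D1 had 381 (372 to 391). B2m, the class I light chain, lay at percentile 99.3. The H2 genes share sequence: 95.4% of the 100-base stretches of the H2-D1 transcript and 83.6% of those of H2-Q7 occur in no other annotated gene, so the split of reads among them is uncertain. These percentages hold for the reference sequences, and differences of the BALB/c H2 genes from them were not examined. H2-L, the remaining gene of the 25 listed, was not in the table, so no reads could be assigned to it. Of 10 class II members, 3 were detected, and Cd74, the invariant chain, had 95.9 CPM (91.1 to 101) and H2-DMa 18.1 (16 to 20.3). H2-Aa, H2-Ab1 and H2-Eb1 had 0 reads each, and Ciita, the class II transactivator, had 10.

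Interferon-response genes were mostly low. In the type I list 37 of 49 members were detected but 10 exceeded the median TPM, and the list's median TPM of 2.99 lay at percentile 11.3. By reads, Trim25, a ubiquitin ligase of the RIG-I pathway, was first with 176 CPM and Samhd1, a dNTP hydrolase, followed with 91.9. Isg15 had 2.44 (1.73 to 3.35), Ifit1 had 6 reads, and Mx1, Mx2, Rsad2 and Oas2 had 0. In the interferon gamma list 19 of 29 were detected and 7 exceeded the median, with the most reads on Jak2 (128 CPM) and Wars (124), while Cxcl9 and Cxcl10, chemokines that attract T cells, had 1 and 3 reads. Of 14 nucleic acid sensing genes 13 were detected and 6 exceeded the median, with the most reads on the editing enzyme Adar (93 CPM) and the adaptor Mavs (72.5). Trex1 had 0 reads, and all of its annotated exon length (100%) lies under another gene's exons.

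Of 43 chemokine and cytokine genes, 25 were detected, 8 had 0 reads and 16 exceeded the median TPM. Spp1, which encodes osteopontin, had 619.7 CPM (607 to 632), and Csf1, the macrophage growth factor, had 385 (375 to 395). Mif, macrophage migration inhibitory factor, followed with 219 (211 to 226) and lay at percentile 99.1, above Csf1 at 95.8. Of the 100-base stretches of Mif 53% occur in no other annotated gene, against 100% for Csf1, so its count is less certain. Lif had 1707 reads, Vegfa 1647, Cxcl16 1331 and Cx3cl1 1180. Csf3, which encodes G-CSF, lay at percentile 90.8 with 57.1 CPM (53.4 to 61), and the neutrophil chemokine genes Cxcl5 and Cxcl1 had 50.04 and 24.7. Ccl2 and Cxcl12 had 0 reads and Il6 had 6. All 29 NF-kB targets were detected and 18 exceeded the median, with the prostaglandin synthase Ptgs2 at 517 CPM and Tnfaip2 at 310.4. Of the 13 NK cell and stress ligands listed, 10 were in the table and 4 were detected, and Ulbp1, an NKG2D ligand, had 94.1 CPM (89.3 to 99) against 3.02 for Clec2d.

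Epithelial and mesenchymal genes were expressed side by side. Of 36 epithelial genes 26 were detected and 19 exceeded the median TPM, with the simple-epithelium keratins Krt18 and Krt8 at 1057 and 663 CPM and Cdh1, E-cadherin, at 6426 reads. Of 50 mesenchymal and matrix genes 33 were detected and 24 exceeded the median. This list took 1.61% of all reads, against 0.438% for the epithelial list, whereas its median TPM of 11.2 (percentile 28.6) was below the epithelial median of 26.9 (percentile 53.1). Vim, the intermediate filament vimentin, had 3117 CPM (3089 to 3145) and Fn1, fibronectin, 2816, followed by Lgals1 with 41943 reads and Thbs1 with 40950. Among transcription factors of epithelial-mesenchymal transition, Twist1 had 882 reads, Zeb2 723 and Snai1 267, whereas Prrx1 had 5, Zeb1 2, and Snai2 and Twist2 0. With length correction Snai1 lay above Zeb2: the TPM was 103 for Twist1, 31.4 for Snai1 and 6.91 for Zeb2. Cdh2, N-cadherin, and Col3a1 had 0 reads.

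Most proliferation genes exceeded the median. All 30 S-phase genes and all 31 G2/M genes were detected, and 23 and 28 exceeded the median TPM. Mcm6, a subunit of the replicative helicase, and Cdt1, which helps to load it, had 483 and 416 CPM. Top2a, topoisomerase II alpha, had 862 and Anln, anillin, 500.1. Of 26 p53 targets 23 were detected and 10 exceeded the median, with Plk2 at 246 and Perp at 197 CPM. Cdkn1a had 287 reads and Pmaip1 and Eda2r had 0. Replication-dependent histone genes, whose mRNAs lack poly(A) tails, were near the limit in this poly(A) library: 1 of 15 was detected, Hist1h1c at 4.69 CPM, followed by Hist1h2bc at 0.578.

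Metabolic and stress genes were widely detected. Among oxidative phosphorylation genes all 38 were detected and 37 exceeded the median TPM, with the most reads on Atp5b and Atp5a1 (1049 and 453 CPM), while Cox8a and Cox6a1 were the highest by TPM (1250 and 948). Of 34 hypoxia and glycolysis genes 32 were detected and 17 exceeded the median, with the most reads on Pkm (1266 CPM) and Eno1 (836). Gapdh had 237 reads, and 22% of its 100-base stretches occur in no other annotated gene. Counts of genes with few own stretches varied: Fdps had 24.2% and 22 reads, Pgk1 33% and 7469, and Ftl1 21.4% and 26891. The cause of the Gapdh count was not tested. Of 25 cholesterol synthesis genes 24 were detected and 9 exceeded the median, with the most reads on Srebf2 (109). Of 26 fatty acid and lipid genes 23 were detected and 16 exceeded the median, with the most reads on Fasn (626) and Scd2 (599). In the integrated stress response and amino acid synthesis list 28 of 30 were detected and 23 exceeded the median, with the most reads on Sars (505) and Psat1 (478). All 21 unfolded protein response genes were detected and above the median, with the chaperones Hspa5 at 811 and Calr at 282. Of 23 Nrf2 targets 22 were detected and 20 exceeded the median, with the most reads on the ferritin chains Fth1 (2342) and Ftl1 (1728). Of 33 immediate early genes 31 were detected and 18 exceeded the median, with the most reads on Myc (484) and Fosl2 (354). Of 16 heat shock genes 15 were detected and 13 exceeded the median, with the most reads on Hsp90ab1 (5056) and Hspa8 (2898). Values in parentheses are CPM, except those of Cox8a and Cox6a1.

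Over genes of all biotypes, the 10 with the most reads took 5.66% of the library and the 100 with the most took 19%. The processed pseudogene Gm8730, with 52699 reads, was among the 10. The 12 protein-coding genes with the most reads were Eef1a1 (15634 CPM), Eef2, mt-Co1, Hsp90ab1, Ahnak, Rplp0, Rpsa, Tubb5, Pabpc1, Vim, Actg1 and Hspa8 (2898 CPM). All 45 cytosolic ribosomal protein genes were detected and together took 5.56% of reads, with Rplp0 at 3666 and Rpsa at 3648 CPM. Of 15 mitochondrially encoded genes 14 were detected, with mt-Co1 at 6499 and mt-Cytb at 2707.

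**Figure D2:**
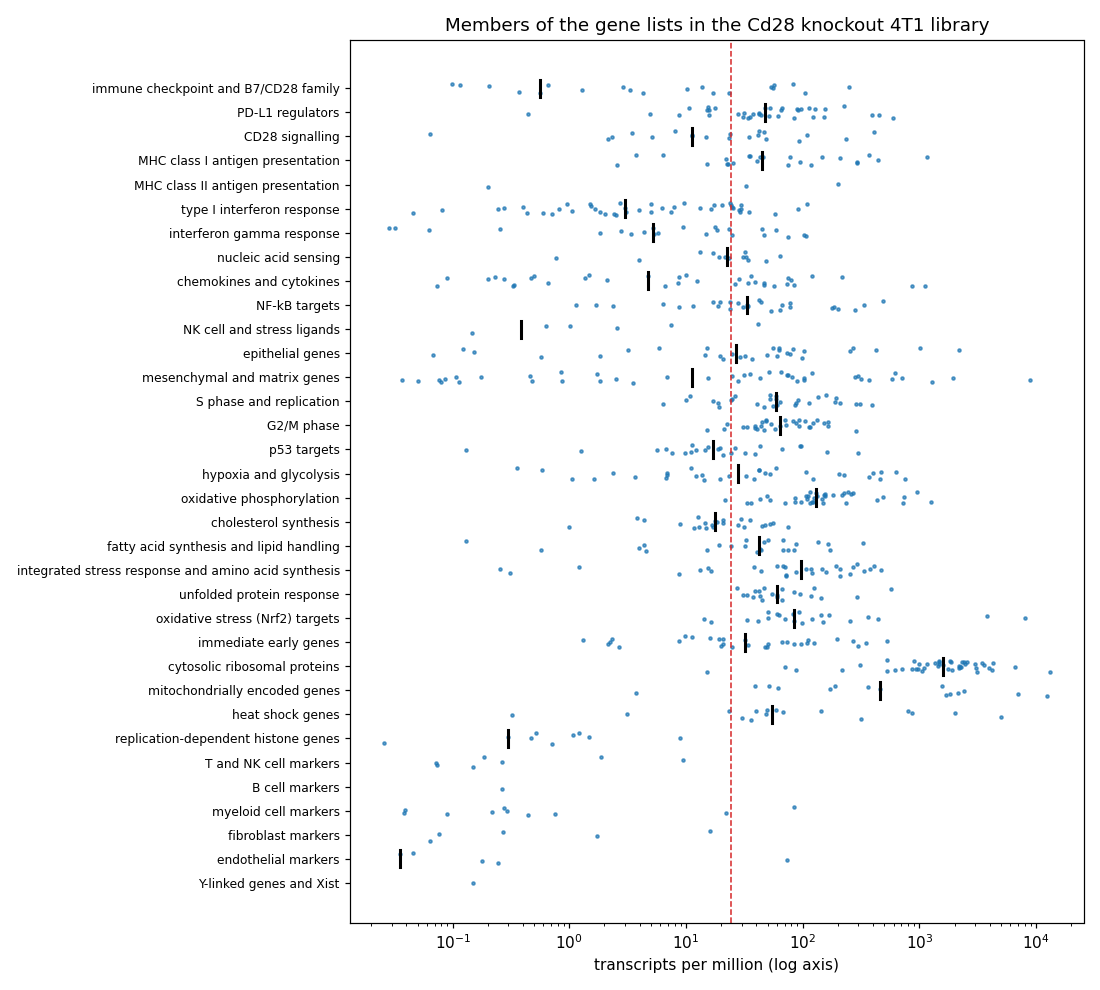
TPM (log axis) of each member with at least 1 read in the 34 gene lists; each point is a gene, black bars are list medians over all members in the table (not drawn where the median is 0), the vertical scatter within a list carries no meaning, and the dashed line is the median of detected protein-coding genes, 24.4 TPM. To the right of the line lie 44 of 45 ribosomal protein, 14 of 15 mitochondrially encoded and 37 of 38 oxidative phosphorylation genes, and markers of other cell types lie mostly to its left.

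Most markers of other cell types had fewer than 10 reads. Of 20 T and NK cell markers 2 were detected, Trac with 2.96 and Cd27 with 1.48 CPM, and Cd3d, Cd3e and Cd3g had 0 reads. Of 8 B cell markers 0 were detected; Cd79b had 2 reads. Of 21 myeloid markers 2 were detected, the lysosomal protein gene Cd68 (35.7 CPM) and Cd14 (11.6), while Ptprc and Adgre1 had 0 reads. Of 11 fibroblast markers 2 were detected, Pdgfra at 53.9 and Col1a1 at 3.79. Of 9 endothelial markers 2 were detected, Eng at 99.8 and Vwf at 0.964, while Pecam1 and Kdr had 0 reads. Of the Y-linked genes and Xist, Xist had 14 reads (0.899 CPM) and Ddx3y and the remaining Y-linked genes had 0.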

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

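The comparisons of pseudogenes below were written down before their results were seen. Each result here is a signal in genes outside the protein-coding lists, above the 3 reads that a count of 0 allows.

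Processed pseudogenes, intronless copies of mRNAs, held 277696 reads, 1.78% of the library. Gm8730 (chromosome 8, 102864845 to 102865798) alone had 52699, close to the 57064 of Rplp0, and 39 such pseudogenes had at least 1000 reads each. Transcription from inside an active host gene is argued against as the source of most: 7.69% of the 39 (3, exact 95% interval 1.61% to 20.9%) lay inside a protein-coding gene with at least 100 reads, against 4.5% of 200 randomly drawn pseudogenes with 0 reads (Fisher's exact test, two-sided p = 0.42). Reads of the parent mRNAs placed on near-identical copies are a candidate explanation: the 39 shared a median of 89% of their 50-base stretches with other annotated genes against 0.431% for the 200, a difference of 88.6 percentage points (bootstrap 95% interval 82 to 90.1; permutation test, two-sided p = 1e-05, the smallest these permutations can give). The test does not separate misplaced reads from transcription of young copies, and no biological explanation was tested.

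Genes on the Y chromosome held 1175 reads, in 3 of 1570 listed genes: Gm47283 had 1148, Mid1-ps1 14 and Gm21860 13, all between 90753057 and 90816464. The signal was confined to this stretch: the Y-linked genes of the fixed list, Ddx3y, Eif2s3y, Kdm5d and Uty, had 0 reads each. The source of the reads was not tested. Whether the X chromosome carries the same sequence was not examined, so these counts do not show Y-specific transcription. The ribosomal RNA gene CT010467.1 on chromosome 17 had 23743 reads in this poly(A) library. The microRNA gene Gm23935 on chromosome 16, 57 bases long, had 16402 reads. Reads placed on this gene do not show the microRNA itself, and the source of the reads on either gene was not tested.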

How the results depend on the processing

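All alternatives run were chosen after seeing the data; those fixed beforehand concern the ratio of 2 libraries (scaling, read minimum, fold, biotype, length trend, chromosome medians, prior, mean for median) and were not run, because the wild-type library was not analysed. No paired analysis was possible because 1 library was used. With 1 library no replicate could be left out, so the spread between cultures is unknown and depth limits only the counting error, which is wide at Cd28 and narrow at abundant genes. Ranking among genes with at least 1 read, in place of at least 10, moved Cd274 from percentile 14.4 to 28.6 and Cd28 from 0.296 to 11.01, which follows from adding low genes to the reference. Without length correction Cd28 lay at percentile 0, since a gene with 8 reads has fewer than any gene in the reference set, and Cd274 at 14.1. Other totals left both genes' CPM within their counting intervals (0.534 and 0.549 for Cd28, 5.48 and 5.63 for Cd274). The number of protein-coding genes detected was 13793 at 1 read, 12597 at 3 and 9687 at 100. Of 102 recounts of detected list members 17 differed by more than 1.5 times, in lists near the limit such as histone genes and markers of other cell types, but also at 100 reads in the checkpoint list (9 in place of 14) and the type I interferon list (24 in place of 37). Of 34 recounts above the median without length correction 3 did: class II (1 in place of 2), myeloid (0 in place of 1) and fibroblast markers (1 in place of 0).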

Other observations

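The tests in this part were chosen after the values were seen.

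The library held Cd74 at 95.9 CPM with 0 reads of H2-Aa, H2-Ab1 and H2-Eb1 and 10 of Ciita. Among receptor tyrosine kinases of the lists, Axl had 15481 reads and Pdgfra 839, whereas Tek had 6, Csf1r 1, and Pdgfrb, Kdr and Tie1 0. The long noncoding RNAs Malat1 and Neat1 had 26763 and 22300 reads.

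Exact sharing with another annotated gene is unlikely as the source of the 8 reads of Cd28 in a knockout library. Of the 100-base stretches of its chosen transcript, 100% occur in no other annotated transcript. Reads placed with mismatches, and sequence outside annotated transcripts, were not examined. RNA of T cells is also argued against as the source: 2 of the 20 T and NK cell markers, Trac (46 reads) and Cd27 (23 reads), had as many reads as Cd28, and the other 18 together had 8 reads, with 0 on Cd3d, Cd3e, Cd3g, Trbc1 and Trbc2, although T cell receptor J and V segments had 17 and 11 reads and immunoglobulin genes 0. Other sources stay open and were not tested. They include a transcript that persists after a small edit, unedited cells in the culture, and reads carried over from other libraries.

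Levels of genes that should be abundant together were uneven. Among ribosomal protein genes Rpl24 had 82 reads, Rps2 671 and Rps18 1145, against 57064 for Rplp0. Loss of reads shared with pseudogenes could be a cause, but across the 45 genes TPM did not follow the percentage of own 100-base stretches detectably (Spearman rho = 0.127, bootstrap 95% interval -0.172 to 0.435, permutation p = 0.403; Pearson r = 0.279 on log2 TPM, p = 0.0632, and 0.335 without the 2 genes farthest from the median), and rho was 0.022 with 50-base stretches (permutation p = 0.886). Exons shared with an overlapping gene gave rho = -0.257 (-0.547 to 0.0462, permutation p = 0.0887) and r = -0.505 (p = 0.00207), which fell to -0.253 without the 2 farthest genes, among them Rpl24 with 47% of its exon length overlapped. Among the 13 mitochondrially encoded protein genes, mt-Co2, mt-Co3, mt-Atp6, mt-Nd3 and mt-Nd4l had under 3% own stretches and TPM between 39.2 and 189, and the others, except mt-Atp8 at 3.74, lay between 1549 and 12485; reads shared with nuclear copies may account for this, but rho over all 13 was 0.497 (-0.0982 to 0.916, permutation p = 0.0871; r = 0.482, p = 0.0959, and 0.415 without the 2 farthest), and 0.451 with 50-base stretches (permutation p = 0.123). These 3 relations run across genes of 1 library, genes are not independent replicates, and the Benjamini-Hochberg adjusted p of the rank correlations was 0.133 for mitochondrial genes, 0.403 for own sequence of ribosomal genes and 0.133 for overlap. None of the 3 rank tests excludes its explanation, since each interval is wide. The own-sequence measure also misses copies outside annotated transcripts. By that measure mt-Atp8, the exception among the mitochondrial genes, had 100% own stretches. It is 204 bases long, and 21.1% of its exon length is overlapped by another gene.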
